A study of Mus musculus with 8 samples.

How the data were processed

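Nuclei of mouse bone marrow were profiled with 10x Multiome, an assay that reads RNA and open chromatin (ATAC) under shared droplet barcodes. The labels give 4 groups, marrow of the skull and of the tibia from mice with a brain tumour and from age-matched mice without one, with 1 RNA and 1 ATAC library per group (8 libraries). Per the labels, tumour mice carried the EPZFTA-RELA tumour, driven by a fusion of Zfta and Rela found in childhood ependymoma, and the other mice carried a Nestin-driven inducible Cre with a red reporter. Per the labels' protocols, mice received a labelled CD45 antibody into the blood before death, skulls were freed of dura, cut and dissociated with a pestle, tibiae were flushed, and cells were stained for CD45, Ter119 and dead cells and sorted. The cell type label calls the sorted cells CD34-positive. Skull and tibia were prepared in different ways, so site and preparation were confounded.

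Per the file headers, the deposited matrices hold counts, as unique molecular identifiers (UMIs) per gene and counts per peak for every barcode, made by Cell Ranger ARC 2.0.2 with the mm10 reference. Per the submitters' processing notes, Cell Ranger ARC 8.0.1, Cell Ranger, Seurat and mm10 were used, so the version differs between these sources. The deposited fragment files hold the read pairs behind each unique fragment as counts, and the deposited peak lists hold positions per library without a score (unit other), per the file headers made for each library on its own. Any filter on barcodes after this step is not given in the sources used here.

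The RNA matrices held 439288 barcodes and 8822695 UMIs for non-tumour skull, 342433 and 2767284 for tumour skull, 287435 and 3552919 for non-tumour tibia, and 434494 and 6091271 for tumour tibia, over 32285 genes. The ATAC libraries held 20453965, 15324780, 24222589 and 16989255 unique fragments in the same order. The call fixed before the data were examined asked for at least 500 UMIs, at least 1000 fragments and under 20% mitochondrial UMIs, and it left 207, 9, 19 and 65 nuclei. Barcodes that passed both minimums had median mitochondrial shares of 24.2%, 75.5%, 83.3% and 35.3%, and barcodes that passed on RNA had medians of 26, 27, 14 and 17 fragments. RNA and ATAC were therefore called apart, a change chosen after the data were seen. The RNA call used at least 500 UMIs and under 20% mitochondrial UMIs and gave 3088, 662, 1100 and 2006 nuclei. The ATAC set used barcodes of at least 1000 and under 100000 fragments and gave 1604, 1047, 1737 and 1950 barcodes. The upper limit left out 24, 9, 35 and 16 barcodes, which held 31.3%, 30.1%, 36.1% and 20.3% of fragments. In the RNA of the ATAC set, median mitochondrial shares were 34.9%, 72.7%, 83.8% and 66.3%. Of the ATAC set, 12.8%, 0.860%, 1.09% and 3.33% were also in the RNA call, so RNA and chromatin values describe largely different barcodes of the same libraries.

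Doublets were called with scrublet, as carried in scanpy, and 0, 3, 0 and 8 nuclei were taken out. At 0.160% of 6856 nuclei the caller did not work, and doublets were in effect left in. The 6845 nuclei kept were clustered together with scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0 and igraph 0.11.9 under Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9). Counts were scaled to 10000 per nucleus and logged, 2000 variable genes were scaled to at most 10, and 30 principal components, 15 neighbours and Leiden resolution 1 with seed 0 gave 15 clusters. Clusters were named from the markers of 18 cell types fixed before the data were examined, where at least 3 markers lay at least 4 times above the other nuclei. B-lineage markers were so widespread that this fold was not usable for them, and 11 clusters were named B-lineage-like because 3 times their mean B-lineage marker CPM reached the median over clusters. These scoring rules were set after the data were seen. The T- and NK-like cluster and the pair of progenitor and dendritic clusters were clustered again with 15 components at resolution 0.5. A cluster of 196 nuclei with a median of 677.5 UMIs stayed unnamed, since its leading haemoglobin counts came from 1 nucleus in each of 2 libraries.

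Groups hold 1 library each, so no test across conditions was run, and no p-value or standard error is given. Shares carry exact Clopper-Pearson 95% intervals. UMIs were summed per library over all nuclei and over B-lineage-like nuclei, scaled to counts-per-million (CPM), and compared as log2 ratios with exact conditional binomial 95% intervals. All intervals cover counting error only. A count of 0 was set to a floor of 3 counts for a fold. The 4 comparisons were tumour against non-tumour in skull and in tibia, and skull against tibia in non-tumour and in tumour mice. For 27 gene lists fixed before the data were examined, the median log2 ratio of members with at least 50 UMIs over both libraries was taken, with an interval from 1000 binomial resamples and its percentile among 10000 random lists matched on expression in 25 bins. Medians are given from 3 measured members on. Members are counted as higher or lower from 1.5-fold on. The lists were stem cell programme, early lymphoid, B lineage, neutrophil primary granule and progenitor, mature neutrophil, monocyte, erythroid, haemoglobin, megakaryocyte, basophil and mast cell, MHC class II presentation, MHC class I presentation, type I interferon response, NF-kB and inflammatory, AP-1 immediate early, STAT5 and GM-CSF signalling, homing and adhesion, immune tolerance, S phase, G2 and M phase, heat shock, hypoxia and glycolysis, and markers of T and NK cells, macrophages, stromal and bone cells, endothelium, and neural and glial cells. MHC class II, AP-1, G2 and M phase and heat shock were chosen as lead lists after their values were seen.

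Named genes followed a rule fixed before the data were examined. Among genes with at least 200 UMIs over both libraries, the 12 highest and 12 lowest over all nuclei (6 and 6 within a class of at least 100 nuclei per library, in the tumour comparisons) were taken by the interval bound nearest to no change, leaving out mitochondrial genes, Xist, Y-linked genes and clone-based names. Per list, the 2 to 4 members farthest from no change by the same bound were named, and MHC class II and label genes were given in every library. Some genes that this rule selects are not reported here. Nuclei with an MHC class II UMI (H2-Aa, H2-Ab1, H2-Eb1 or Cd74) were counted after thinning each nucleus to 1000 UMIs. T- and NK-like nuclei served as the background, since no erythroid-like class was found to serve as planned. For chromatin, fragments of the ATAC set within 1 kb of annotated gene starts were scaled to the total fragments of the set and compared in the same way, with marker lists of plasmacytoid dendritic, T and NK cells added after the data were seen. Peaks were compared by an overlap of at least 1 base.

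Ratios and list medians were tested on simulated counts with 200 changed genes. In tumour against non-tumour skull, over 5531 genes, 88.7% of 1.5-fold changes, 97.5% of 2-fold and 100% of 4-fold changes had intervals clear of 0. Of unchanged genes, 95.0% had intervals that held the shift which the changed genes put on all others through scaling. The simulated counts held counting error only, so they say nothing on differences between single libraries of the same condition. At 1.5-fold the recovered share was 97.2% in tumour against non-tumour tibia (4538 genes), 94.9% in non-tumour skull against non-tumour tibia (5813 genes) and 90.5% in tumour skull against tumour tibia (4197 genes).

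Alternatives listed before the data were examined were the joint call above, higher minimums of 1000 UMIs and 3000 fragments, an order-of-magnitude UMI rule, doublets kept, resolutions 0.5 and 2, TMM factors (edgeR 4.0.16) and DESeq2 1.42.0 size factors under R 4.3.3 for scaling alone, gene minimums of 10 and 200 UMIs, equal weights per nucleus, equal cluster weights, 10% free RNA taken away, no thinning or 2000 UMIs, windows of 500 bases and 2 kb, scaling by promoter fragments, fragments of all barcodes, a 50% peak overlap and autosomes alone. Added after the data were seen were leaving out nuclei over 15% rRNA-linked UMIs, the top 5% of doublet scores or the unnamed cluster, scaling without mitochondrial and rRNA-linked genes, keeping large ATAC barcodes, and ATAC barcodes under 30% mitochondrial UMIs. Counts per peak were not used, since peak sets differ between libraries. No genome sequence was used.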

Results

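RNA and open chromatin were measured in nuclei of sorted marrow cells from the skull and the tibia of mice with an EPZFTA-RELA brain tumour and of age-matched mice without one. The study asked how a childhood brain tumour relates to blood formation and immune tolerance in skull marrow. Each of the 4 groups had 1 RNA and 1 ATAC library, so no difference has a replicate check. The intervals given compare libraries, not conditions. Intervals of ratios and list medians take each UMI or fragment as an independent draw. Such intervals leave out the spread between nuclei, so they are too narrow where few nuclei hold many UMIs of a gene. The RNA libraries held 8822695 UMIs in non-tumour skull, 2767284 in tumour skull, 3552919 in non-tumour tibia and 6091271 in tumour tibia. The RNA call gave 3088, 662, 1100 and 2006 nuclei in that order, with medians of 1768, 1185.5, 1136.5 and 1514 UMIs and 1016, 614.5, 643.5 and 874.5 genes. Of these, 3088, 659, 1100 and 1998 were kept. Tumour skull was thus the smallest library, and its precision sets that of both comparisons it enters. The chromatin set held 11947159, 7212406, 13646288 and 11854573 fragments, with medians of 4833.5, 4554, 4084 and 3551.5 per barcode, of which 48.2%, 51.8%, 41.0% and 44.9% lay in peaks. The 3 transcripts linked to ribosomal RNA repeats (Gm42418, AY036118 and Gm26917) took 5.54%, 11.1%, 10.4% and 6.80% of the RNA counts of the kept nuclei.

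Most nuclei were B-lineage-like, with Cd79a, Ebf1 and Pax5 among the markers that name the class. These cells made up 92.4% of nuclei in non-tumour skull (95% interval 91.4 to 93.3), 63.3% in tumour skull (59.5 to 67.0), 80.9% in non-tumour tibia (78.5 to 83.2) and 73.0% in tumour tibia (71.0 to 74.9). T- and NK-like nuclei, led by Skap1 and Ccl5, took 0.907% (0.603 to 1.31), 19.0% (16.0 to 22.2), 5.09% (3.87 to 6.56) and 8.61% (7.42 to 9.93) in the same order. Plasmacytoid dendritic-like nuclei, which carried Siglech, Runx2, Tcf4 and Irf8, took 2.27% (1.77 to 2.86), 1.52% (0.730 to 2.77), 1.82% (1.11 to 2.79) and 14.7% (13.2 to 16.3). Stem and multipotent progenitor-like (HSC/MPP-like) nuclei with Hlf, Mecom and Meis1 were rare, with 24, 2, 0 and 19 nuclei, and 0 of 1100 allows a share of up to 0.335%. An unnamed cluster of low-UMI nuclei took 0.227% (0.0912 to 0.466), 10.0% (7.83 to 12.6), 10.5% (8.71 to 12.4) and 0.400% (0.173 to 0.787), and 31.5%, 41.6%, 36.3% and 27.3% of its UMIs were linked to ribosomal RNA. Unnamed sub-clusters, some of them within the T- and NK-like cluster, held 107, 74, 21 and 60 nuclei. The sort, the depth gap and the unnamed cluster can each set these shares. Without nuclei of over 15% ribosomal RNA-linked UMIs, T- and NK-like shares were 0.248%, 11.5%, 0.994% and 4.35%, and those of the unnamed cluster 0.0708%, 1.30%, 1.70% and 0.0588%. With the joint call, plasmacytoid dendritic-like nuclei numbered 1 of 207, 0 of 9, 0 of 19 and 3 of 63, or 0.483%, 0, 0 and 4.76%.

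**Figure D1:**
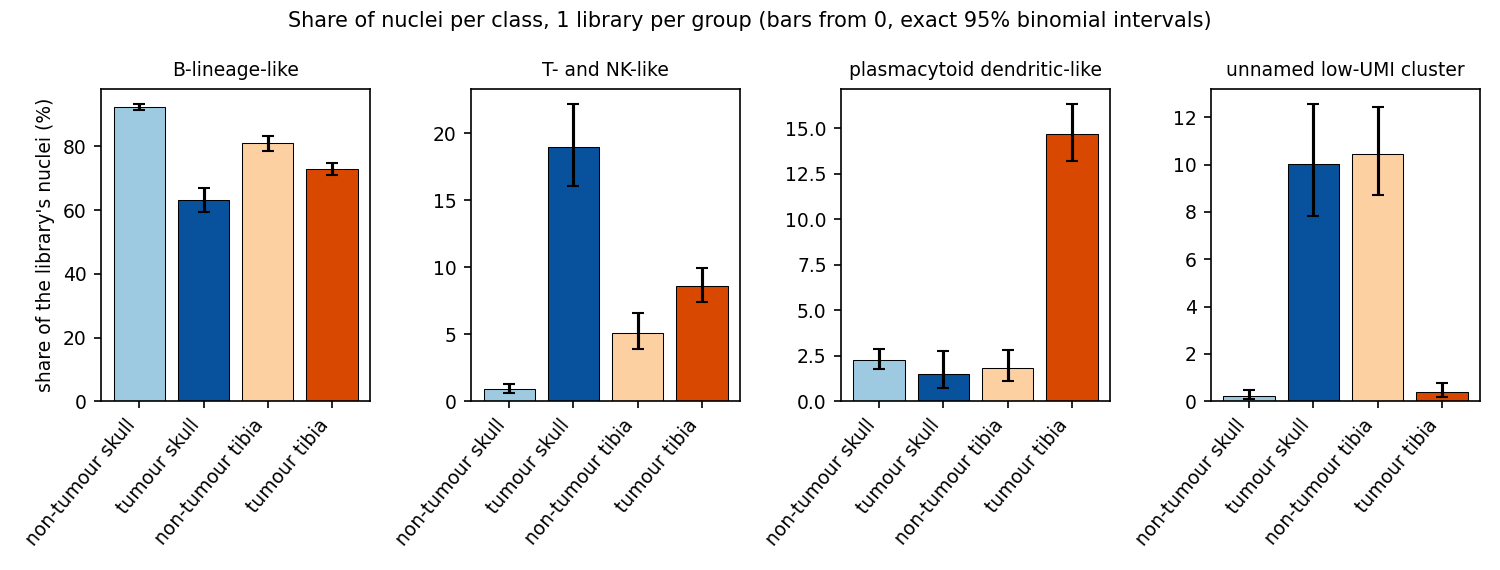
Share of each library's kept nuclei (%, vertical axis from 0) in B-lineage-like, T- and NK-like, plasmacytoid dendritic-like and unnamed low-UMI nuclei for the 4 libraries, with bars as shares and lines as exact 95% intervals for counting error. T- and NK-like nuclei were at 19.0% in tumour skull and plasmacytoid dendritic-like nuclei at 14.7% in tumour tibia.

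The genes behind the labels were measured in each library. Cd34, named in the cell type label but not in the staining protocol, had 9 UMIs in non-tumour skull, 0 in tumour skull, 0 in non-tumour tibia and 9 in tumour tibia, while Kit, a receptor of early progenitors, had 57, 19, 5 and 32. Ptprc, which encodes CD45, was at 785, 952, 856 and 1324 CPM. Nes had 0 UMIs in each library, where the floor of 3 counts equals 0.476, 2.50, 1.69 and 0.852 CPM. Rela, a partner of the driver fusion, was at 50.2, 52.4, 43.9 and 32.4 CPM, and Zfta (2700081O15Rik) was at 26.8, 17.5, 18.0 and 19.3 CPM. Both Xist, at 560, 691, 410 and 700 CPM, and Y-linked genes were found in each library, with Ddx3y at 100, 81.6, 84.4 and 93.5 CPM, Eif2s3y at 69.1, 67.4, 68.6 and 65.4, Kdm5d at 28.1, 32.5, 32.1 and 35.8, and Uty at 94.0, 69.1, 56.8 and 92.3.

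In skull marrow, the tumour library held more T- and NK-like nuclei and less B-lineage, AP-1 and heat shock RNA than the non-tumour library. T- and NK-like nuclei were 20.9-fold more frequent (13.8 to 32.7), NK- and innate lymphoid-like (NK/ILC-like) nuclei 15.5-fold (9.18 to 27.5) and T-like nuclei 18.1-fold (7.68 to 49.2). Without nuclei rich in ribosomal RNA, T-like nuclei were 9 of 384 against 1 of 2826, and at a minimum of 1000 UMIs NK/ILC-like shares were 7.09% against 0.209%. At resolution 0.5 no T-like class was named. B-lineage-like nuclei were 1.46-fold less frequent (1.32 to 1.62). That gap narrowed without nuclei rich in ribosomal RNA and with doublets kept, as the shares in the part on processing show, so its size is not firm. Skap1, an adaptor of T cell receptor signalling, was 33.8-fold higher at 193 against 5.72 CPM, but it leads the T- and NK-like cluster and follows its size. Rora, a regulator of innate lymphoid cells, was 10.1-fold higher, and the chemokine gene Ccl4 was higher by a log2 ratio of 4.08 (3.38 to 4.82).

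Of 13 AP-1 immediate early genes, which respond quickly to stimulation and stress, 8 were lower and 1 was higher in tumour skull, with a list median log2 ratio of −0.69 (−0.84 to −0.61, percentile 0 of matched random lists). Jun was 3.38-fold lower and Fosb 3.48-fold lower, and Atf3 had a log2 ratio of −1.51, whereas Nr4a1 was higher by 1.22. In barcodes under 100 UMIs Jun was at 61.4 CPM in tumour skull against 484 in non-tumour skull and Fosb at 8.95 against 68.1. A cluster led by Hspa1a, Hspa1b and Fosb held 353 nuclei of non-tumour skull, 10 of tumour skull, 10 of non-tumour tibia and 6 of tumour tibia. The non-tumour skull library also enters the site comparison without a tumour, so a trait of that 1 sample would show in both comparisons. Heat shock chaperone genes were lower in 5 of 9 members, with a median of −1.04 (−1.16 to −0.74, percentile 0) and examples in Hsph1 (−1.39), Dnajb1 (−1.49) and Hspa1a (−1.14). G2 and M phase genes went the other way, with 10 of 18 higher, 0 lower and a median of 0.62 (0.44 to 0.68, percentile 100), among them Plk1 (1.32), Cenpf (0.91) and Mki67 (0.64). The cluster led by Ube2c, Top2a and Mki67 ran the opposite way in share, with 6.83% of tumour skull nuclei (5.02 to 9.03) against 10.1% of non-tumour skull (9.09 to 11.3). It held 215744 of 1201389 UMIs in 45 tumour skull nuclei, and 1040572 of 6297612 in 313 nuclei of non-tumour skull. Its nuclei were thus deeper in tumour skull, which gives them more weight in summed UMIs than in shares of nuclei. B lineage genes were lower in 4 of 12, with a median of −0.40 (−0.46 to −0.32, percentile 3.46), and Igll1 of the pre-B receptor was lowest at −2.71 (−4.60 to −1.32, 4 against 137 UMIs). Early lymphoid genes had a median of −0.29 (−0.39 to −0.11, percentile 14.2), with Dntt at −1.71 and Ccr9 at −1.35 but Il7r at 0.69.

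The MHC class II presentation list was near 0 in skull, at 0.04 (−0.10 to 0.24), with 1 member higher (H2-DMb1, 1.15) and 1 lower (H2-Oa, −1.0) of 13. Medians of other lists in skull had intervals that held 0 for the stem cell programme (−0.24), monocyte (−0.25), MHC class I (−0.09), type I interferon (0.05), STAT5 and GM-CSF (0.13), homing and adhesion (0.16), immune tolerance (0.11) and hypoxia and glycolysis (−0.21). S phase genes were at −0.30 (−0.39 to −0.02, percentile 7.47), with Mcm6 at −0.77, and NF-kB genes at −0.19 (−0.36 to 0.01), with Nfkbia at −0.73. Within these lists Ccr2, a chemokine receptor of monocytes and lymphocytes, was higher by 2.46, Itgal by 1.86, Jak2 by 0.86, Irf9 by 0.88 and Nlrc5 by 0.80, while Tgfbr2 was at −0.71, Klf4 at −0.94 and Pkm at −0.80. Among the remaining named genes, Emb was 10.2-fold higher, Tnik 4.41-fold, Nr4a3 4.16-fold and Prkch 4.05-fold. Cdk8 (6.94-fold), Lars2 (4.74-fold), Znhit1 (4.13-fold), Kpna1 (3.96-fold) and Cmss1 (3.47-fold) were higher too. All 5 were also higher in tumour skull barcodes under 100 UMIs, with Cdk8 at 1354 against 153 CPM, Lars2 at 11356 against 2373, Znhit1 at 566 against 132, Kpna1 at 812 against 116 and Cmss1 at 3310 against 1206. Camk2b was 7.67-fold lower, Natd1 4.30-fold, Slc25a18 4.12-fold, Abcg1 3.29-fold, Iglc1 and Atp6ap2 3.13-fold each and Irs2 2.86-fold. Haemoglobin RNA was lower (median −4.15, −4.99 to −3.41), but 356 of the 364 Hba-a1 UMIs of non-tumour skull, and 566 of 577 for Hbb-bs, lay in 1 nucleus.

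Within B-lineage-like nuclei of the skull the AP-1 median was −0.80 (−0.87 to −0.52), the heat shock median −0.84 (−1.20 to −0.55) and the G2 and M phase median 0.87 (0.69 to 0.94), with 15 of 18 members higher. B lineage genes were at −0.14 (−0.21 to −0.07, percentile 20.3) within these nuclei and early lymphoid genes at −0.03 (−0.14 to 0.14), both nearer to 0 than over all nuclei. Fosb was 4.68-fold lower there, Hspa1a 3.77-fold, Bcl2l11 3.51-fold, Hsph1 3.40-fold, Jun 3.30-fold and Camk2b 6.63-fold, while Ect2, a cytokinesis gene, was 2.62-fold higher. Cdk8 was higher by 4.15-fold, Znhit1 by 3.37-fold, Il31ra by 2.76-fold, Kpna1 by 2.75-fold and Lars2 by 2.44-fold. Low-UMI barcodes had more Cdk8, Znhit1, Kpna1 and Lars2 too, as given above. Different clusters held the class in the 2 libraries, since a cluster led by Hspa1a, Fosb and Hsph1 held 353 nuclei of non-tumour skull and 10 of tumour skull, a cluster led by Nr6a1os and Gfra1 402 and 25, and a pro-B cluster led by Igll1, Vpreb1 and Dntt 108 and 1. The G2 and M phase median over all nuclei turned to −0.08 with every nucleus weighted equally and to −1.98 with the joint call of 9 tumour skull nuclei. With clusters given the same weights the AP-1 median was −0.25 and the heat shock median −0.27, and with the joint call the early lymphoid median was 0.18.

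In tibia marrow, the tumour library held more plasmacytoid dendritic-like nuclei and less G2 and M phase RNA than the non-tumour library. Plasmacytoid dendritic-like nuclei were 8.09-fold more frequent (5.15 to 13.4), T- and NK-like nuclei 1.69-fold (1.24 to 2.33) and T-like nuclei 3.8-fold (1.95 to 8.27), and NK/ILC-like nuclei were at 1.13-fold (0.777 to 1.65). NK/ILC-like shares went from 0.284% to 2.12% without nuclei rich in ribosomal RNA (2 and 36 nuclei), and from 1.09% to 3.05% at resolution 0.5. Runx2 was 12.2-fold higher at 1177 against 96.2 CPM and Siglech, a surface receptor of plasmacytoid dendritic cells, 10.5-fold, and they lead these clusters with Grm8 (13-fold), P2ry14 (21.3-fold), Srgap3 (10.9-fold), Gria3 (10.0-fold), Fmnl2 (9.02-fold) and Tbc1d8 (8.99-fold). Sntb1 was 18.4-fold higher, Plxdc2 13.1-fold and Apba1 8.06-fold. Ighg2c was at least 46.3-fold higher against the floor of 3 counts, but 273 of its 275 UMIs lay in 1 nucleus.

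Of 18 G2 and M phase genes 13 were lower and 0 higher in tumour tibia, with a median of −0.73 (−0.87 to −0.60, percentile 0), such as Ube2c (−1.34), Cdk1 (−1.28) and Mki67 (−0.91). S phase genes had a median of −0.43 (−0.54 to −0.17), with Mcm3 at −0.86. Hist1h3f was 9.14-fold lower, Hist1h2ab 8.97-fold, Hist1h2ae 7.09-fold, Hist1h4c 3.50-fold and Hist1h4d 3.09-fold, as were the ribosomal protein genes Rps27 (5.78-fold), Rpl35 (4.70-fold), Rpl9 (3.93-fold) and Rpl36a (3.47-fold) and the tubulin gene Tubb4b (2.83-fold). Ribosomal protein genes together took 9.26% of the UMIs in non-tumour tibia and 5.97% in tumour tibia. Il1rapl1 was 9.37-fold lower. In barcodes under 100 UMIs, Il1rapl1 was at 121 CPM in tumour tibia against 1463 in non-tumour tibia, Hist1h2ab at 27.2 against 232, Hist1h3f at 8.23 against 63.0, Hist1h2ae at 60.1 against 265 and Rps27 at 22.2 against 137. Rpl36a went the other way there, at 273 against 257 CPM. Ribosomal protein genes together did so too, with 8.70% of the UMIs of these barcodes in tumour tibia against 4.88% in non-tumour tibia. Haemoglobin genes were lower at −3.69 (−4.01 to −3.28), but 150 of the 184 Hbb-bs UMIs of non-tumour tibia lay in 1 nucleus.

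Type I interferon response genes were higher in 5 of 9 members in tumour tibia, with a median of 0.73 (0.32 to 0.87, percentile 99.9), led by Bst2 (1.53), which is also a plasmacytoid dendritic marker, Stat2 (0.86) and Trim30a (0.73). Homing and adhesion genes were higher in 6 of 10, with a median of 0.68 (0.50 to 0.76), among them Ccr2 (2.11), and stem cell genes in 3 of 5, with a median of 1.45 (1.06 to 1.93) and Gcnt2 at 2.56 and Angpt1 at 2.33. Early lymphoid genes had a median of 0.50 (0.29 to 0.67), with Ccr9 at 2.93, Flt3 at 2.74 and Dntt at 2.73. Monocyte genes had a median of 1.01 (0.58 to 1.51), with Irf8 at 1.46, and T and NK cell genes 1.85 (1.41 to 2.17) in 5 of 6, with Bcl11b at 2.50 and Themis at 2.49. Ccr9, Flt3 and Irf8 are also carried by the plasmacytoid dendritic-like nuclei, and Dntt by some of their sub-clusters. The stem cell genes Gcnt2 and Meis1 were also raised in the cluster led by Runx2 and Siglech, which held 38 nuclei of non-tumour tibia and 331 of tumour tibia. MHC class II genes were lower in 3 of 13, with a median of −0.37 (−0.47 to −0.13, percentile 0.130). These were H2-Oa (−1.0), H2-Eb1 (−0.72) and H2-Ab1 (−0.61), while Cd74 at −0.49 did not reach 1.5-fold. B lineage genes had a median of −0.17 (−0.23 to −0.13, percentile 14.6), with Cd79b at −0.66, heat shock genes −0.26 (−0.38 to −0.05, percentile 8.29) and hypoxia and glycolysis genes −0.41 (−0.58 to −0.19), with Eno1 at −1.10. AP-1 genes were at 0.18 (0.03 to 0.31, percentile 71.8), MHC class I at −0.06, NF-kB at −0.07, STAT5 and GM-CSF at 0.09 and immune tolerance at 0.08, with Csf2rb at 1.74, Ccl4 at 2.58 and Cd200r1 at 4.04 (2.13 to 7.11, 65 against 2 UMIs).

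Within B-lineage-like nuclei of the tibia the G2 and M phase median was −0.56 (−0.69 to −0.43), with 8 of 18 members lower, the MHC class II median −0.07 (−0.21 to 0.12) and the AP-1 median 0.38 (0.16 to 0.46). B lineage genes turned to 0.11 (0.06 to 0.16) within these nuclei. Homing and adhesion genes fell to 0.22 with 1 of 9 higher, stem cell genes to 0.35 over 3 members, early lymphoid genes to 0.03 (−0.09 to 0.19), monocyte genes to 0.27 and type I interferon genes to 0.19 (−0.09 to 0.32). Il1rapl1 was 9.32-fold lower there, Hist1h2ab 7.57-fold, Hist1h3f 7.30-fold, Hist1h2ae 5.88-fold, Rps27 4.97-fold and Rpl35 4.14-fold. Hes1, a target of Notch signalling, was 3.04-fold higher, Zrsr1 3.00-fold, Cbr3 2.67-fold and Trps1 2.52-fold. A cluster led by Ms4a1 and Ifi30 held 117 nuclei of non-tumour tibia (10.6%) and 311 of tumour tibia (15.6%), and one led by Rag1 held 49 (4.45%) and 195 (9.76%). At resolution 0.5 the T- and NK-like share was 10.2% in non-tumour tibia and 8.86% in tumour tibia, which turned that direction, and the G2 and M phase median was −0.26 with clusters given the same weights and −0.28 with nuclei weighted equally. TMM factors and DESeq2 size factors each moved the all-gene median of this comparison by −0.10.

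Without a tumour, the skull library carried more AP-1 and heat shock RNA, and less MHC class II and G2 and M phase RNA, than the tibia library. Skull and tibia were prepared in different ways, so site and preparation cannot be told apart here. Each of 13 AP-1 genes was higher in skull, with a median of 1.30 (1.20 to 1.42, percentile 100), including Fosb (6.03-fold), Nr4a1 (2.38), Egr1 (2.22) and Atf3 (1.91 on the log2 scale). Heat shock genes were higher in 7 of 9, with a median of 0.77 (0.72 to 1.01), and Hspa1a was 20.8-fold, Hspa1b 20.5-fold and Hsph1 5.17-fold higher. MHC class II genes were lower in 9 of 13 and higher in 1, with a median of −0.81 (−0.97 to −0.75, percentile 0), among them H2-Oa (−1.37), H2-DMb1 (−1.33), the master regulator Ciita (−1.19) and H2-Aa (−0.97). G2 and M phase genes were lower in 13 of 18, with a median of −0.63 (−0.77 to −0.53, percentile 0), such as Plk1 (−1.24), Ube2c (−1.16) and Ccnb1 (−1.15). The cycling cluster, in contrast, held 10.1% of skull nuclei and 7.0% of tibia nuclei (5.56 to 8.67).

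Early lymphoid genes were higher in 6 of 10 in non-tumour skull, with a median of 0.83 (0.42 to 0.97) and Dntt at 2.05 and Satb1 at 1.23. B lineage genes had a median of 0.04 (−0.03 to 0.08), but Igll1 was at 2.69 and Vpreb1 at 1.86. NF-kB genes had a median of 0.45 (0.27 to 0.60), with Nfkbia at 0.86, STAT5 and GM-CSF genes 0.42 (0.29 to 0.75), with Pim1 at 0.75, immune tolerance genes 0.28 (0.15 to 0.42, percentile 78.2), with Tgfbr2 at 0.86, and S phase genes 0.39 (0.31 to 0.61), with Dtl at 1.63. Stem cell genes were at 0.60 (0.30 to 0.96), with Gcnt2 at 2.53, and homing and adhesion genes at 0.17 (0.02 to 0.38, percentile 52.4 of random lists with a median of 0.16), with the retention receptor gene Cxcr4 at 1.35 and Itgal at −1.55. Type I interferon genes were at −0.43 (−0.68 to −0.32), with Irf9 at −0.81, MHC class I at −0.33 (−0.40 to −0.11), with Tap1 at −0.75, haemoglobin at −0.96 (−1.15 to −0.78), monocyte at −0.09 (−0.15 to 0.79), with Klf4 at 2.18, and hypoxia and glycolysis at −0.02 (−0.18 to 0.38). The apoptosis genes Bbc3 (6.95-fold) and Bcl2l11 (5.52-fold), the TGF-beta inhibitor gene Smad7 (5.77-fold), Id2 (5.59-fold), Nr6a1os (6.51-fold), Pde3b (4.88-fold), Atp2b4 and Cables1 (7.90-fold each) were higher in skull. Fcer2a was 3.32-fold lower, Ighd 2.72-fold and Ltb 3.17-fold, as were Il1rapl1 (5.87-fold), Il4i1 (4.76-fold), Lars2 (3.16-fold), Slfn8 (2.99-fold), Cdk8 (2.92-fold), Slc14a1 (2.81-fold), Rps27 (2.68-fold), Il31ra (2.57-fold) and Rpl35 (2.52-fold). In barcodes under 100 UMIs, Il1rapl1 was at 245 CPM in skull against 1463 in tibia, Lars2 at 2373 against 8536 and Cdk8 at 153 against 596. Several genes higher in skull were higher there too. Hspa1b was at 148 against 0 CPM, Hspa1a at 117 against 0 and Fosb at 68.1 against 1.80. Hsph1 was at 52.5 against 3.6, Smad7 at 116 against 9.0 and Id2 at 115 against 9.0. Atp2b4 was not higher in these barcodes, at 3.55 against 3.6 CPM.

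Within B-lineage-like nuclei without a tumour the AP-1 median was 1.20 (1.15 to 1.37), with 13 of 13 members higher, the MHC class II median −0.82 (−1.0 to −0.77), with 9 lower, and the G2 and M phase median −0.72 (−0.86 to −0.63). Early lymphoid genes were at 0.34 (0.10 to 0.54) and stem cell genes at 0.12 over 3 members within these nuclei. The cluster led by Hspa1a and Fosb held 353 skull and 10 tibia nuclei, and a cluster led by H2-Eb1, H2-Aa and Ciita held 56 and 133, so these lists and these clusters are not independent. With clusters given the same weights the AP-1 median was 0.61, the heat shock median 0.44, the MHC class II median −0.14 and the early lymphoid median −0.22, and with the joint call the early lymphoid median was −0.53. The G2 and M phase median was −0.01 with nuclei weighted equally, and the haemoglobin median was 5.24 with a minimum of 1000 UMIs.

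In mice with a tumour, the skull library again carried more AP-1 RNA than the tibia library, and more G2, M and S phase RNA. It held less type I interferon RNA and fewer plasmacytoid dendritic-like nuclei. Site and preparation were confounded here too. AP-1 genes were higher in 7 of 13 and lower in 1, with a median of 0.62 (0.52 to 0.77, percentile 100), such as Nr4a1 (7.87-fold), Fos (1.72), Fosb (1.58) and Junb (0.92 on the log2 scale). G2 and M phase genes were higher in 11 of 18, with a median of 0.69 (0.56 to 0.81, percentile 100), including Mki67 (0.91) and Top2a (0.81), and S phase genes in 9 of 15, with a median of 0.68 (0.44 to 0.86) and Rrm2 at 1.65 and Pcna at 0.90. Type I interferon genes were lower in 6 of 9, with a median of −1.01 (−1.25 to −0.74, percentile 0), led by Bst2 (−1.74), Trim30a (−1.17) and Stat2 (−1.01). MHC class II genes were lower in 3 of 13, with a median of −0.29 (−0.50 to −0.21, percentile 4.84). These were H2-Oa (−1.36), Ciita (−0.88) and Ctss (−0.84), while Cd74 at −0.52 did not reach 1.5-fold.

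Of genes that lead the plasmacytoid dendritic-like class, Pacsin1 was 23.4-fold lower in tumour skull than in tumour tibia, Runx2 14.3-fold, Rnd3 14.8-fold, Grm8 11.9-fold, Lair1 10.9-fold, Siglech 10.4-fold, Fmnl2 8.88-fold and Gria3 8.52-fold. Pdzd4 was 10.7-fold lower, the kinase gene Fgr 8.29-fold and Apba1 6.38-fold, and Ighg2c at least 31.3-fold. Stem cell genes had a median of −1.06 (−1.43 to −0.72), with Meis1 at −2.77 and Angpt1 at −2.03, and monocyte genes −0.84 (−1.07 to −0.57), with Irf8 at −1.82 but Klf4 at 1.48. Heat shock genes had a median of 0.31 (0.26 to 0.54), with Hspa1a at 4.22 and Hspa1b at 4.09, and NF-kB genes 0.24 (0.12 to 0.40), with Ccl4 at 1.61 and Nfkb1 at 0.98. Early lymphoid genes went both ways around −0.29 (−0.50 to −0.12, percentile 7.58), with Ccr9 at −3.02 and Dntt at −2.39 but Satb1 at 1.01. B lineage genes were at −0.15 (−0.20 to −0.08, percentile 17.0), with Ms4a1 at −0.82, and homing and adhesion genes at −0.15 (−0.29 to −0.01, percentile 24.2), with Cxcr4 at 1.14. Intervals held 0 for STAT5 and GM-CSF (0.26, with Csf2rb2 at −2.72), immune tolerance (0.05, with Tgfb1 and Lgals9 at 0.59), hypoxia and glycolysis (0.08), MHC class I (−0.07) and T and NK cell genes (0.44, with Skap1 at 0.67 and Klrd1 at −0.85). Rora was 7.04-fold higher, Emb 3.37-fold, Pde3b 4.09-fold, Dennd4a 3.11-fold and Hist1h2ae 3.20-fold, as were Il1rapl1 (4.94-fold), Rps27 (4.57-fold), Znhit1 (4.21-fold), Kpna1 (3.61-fold) and Rpl35 (2.96-fold). In barcodes under 100 UMIs, Il1rapl1 was at 643 CPM in tumour skull against 121 in tumour tibia, Znhit1 at 566 against 137, Kpna1 at 812 against 116, Rps27 at 55.0 against 22.2 and Hist1h2ae at 125 against 60.1.

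Within B-lineage-like nuclei of tumour mice the AP-1 median was 0.48 (0.27 to 0.58), the G2 and M phase median 0.67 (0.52 to 0.81) and the MHC class II median −0.62 (−0.73 to −0.47), with 8 members lower. Early lymphoid genes turned to 0.60 (−0.079 to 0.73, percentile 99.9) within these nuclei, with 4 of 7 higher and 1 lower, and NF-kB genes to −0.09 (−0.20 to 0.04). Type I interferon genes were at −0.35 (−0.72 to −0.13) and stem cell genes at −0.53 over 3 members. The class II-rich cluster held 23 nuclei of tumour skull (3.49%) and 201 of tumour tibia (10.1%), and the Ms4a1 and Ifi30 cluster 14 (2.12%) and 311 (15.6%). The MHC class II median over all nuclei turned to 0.18 with clusters given the same weights, the B lineage median to 0.18 there and to 0.05 without nuclei rich in ribosomal RNA, and the G2 and M phase median was 0.03 with the same weights. DESeq2 size factors moved the all-gene median by 0.10, and TMM factors moved that of B-lineage-like nuclei in the skull tumour comparison by −0.16.

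**Figure D2:**
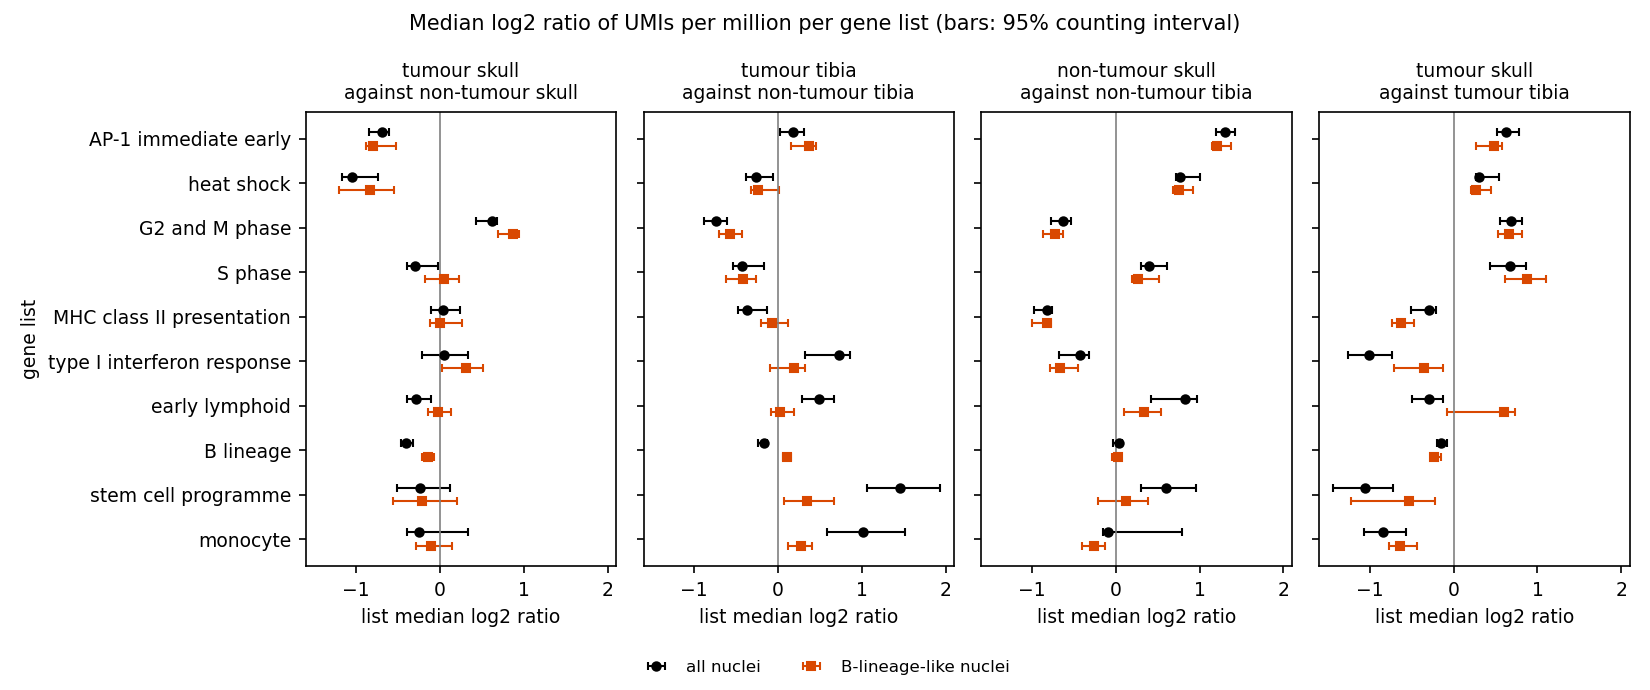
Median log2 ratio of CPM (horizontal axis) for 10 gene lists in the 4 comparisons, with black circles for all nuclei, orange squares for B-lineage-like nuclei and bars for 95% counting intervals. AP-1 genes were at 1.30 in non-tumour skull against non-tumour tibia and at −0.69 in tumour against non-tumour skull.

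The invariant chain gene Cd74 was at 1608 CPM in non-tumour skull, 1374 in tumour skull, 2762 in non-tumour tibia and 1972 in tumour tibia. The class II genes H2-Aa (188, 223, 369 and 273), H2-Ab1 (244, 227, 417 and 274) and H2-Eb1 (118, 122, 231 and 141) were each at their highest in non-tumour tibia. H2-DMa was at 36.7, 29.97, 50.6 and 37.8 CPM, H2-DMb1 at 18.7, 41.6, 47.3 and 47.2, H2-DMb2 at 44.1, 50.8, 77.6 and 60.2, H2-Oa at 21.6, 10.8, 55.7 and 27.8, and H2-Ob at 109, 142, 132 and 130. Ciita was at 33.0, 45.8, 75.4 and 84.1 CPM, Ctss at 120, 86.6, 127 and 155, and the co-stimulatory genes Cd86 at 104, 106, 62.5 and 62.5, Cd40 at 41.4, 54.9, 90.0 and 82.1 and Cd80 at 1.27, 11.7, 1.69 and 0.852 (8, 14, 3 and 3 UMIs). At 1000 UMIs per nucleus, an MHC class II UMI was found in 57.5% of B-lineage-like nuclei of non-tumour skull (55.4 to 59.6), 61.4% of tumour skull (55.5 to 67.1), 77.5% of non-tumour tibia (73.8 to 80.8) and 71.9% of tumour tibia (69.1 to 74.7). These rest on 2200, 285, 581 and 1030 nuclei, with 654, 132, 309 and 428 shallower ones left out and medians of 2113.5, 2346, 1866 and 1944 UMIs, and the unthinned shares were 60.8%, 66.2%, 79.0% and 76.1%. In T- and NK-like nuclei, which should lack these genes, it was 2 of 9, 2 of 52, 0 of 16 and 2 of 88, or 22.2%, 3.85%, 0 and 2.27%, with medians of 1414, 1462, 1234.5 and 1331.5 UMIs. Plasmacytoid dendritic-like nuclei were at 19 of 62, 1 of 7, 5 of 14 and 68 of 281, or 30.6% (19.6 to 43.7), 14.3% (0.361 to 57.9), 35.7% (12.8 to 64.9) and 24.2% (19.3 to 29.6). Unnamed progenitor and dendritic sub-clusters were at 16 of 97, 13 of 23, 1 of 5 and 5 of 43. In skull this was 16.5% (9.73 to 25.4) without and 56.5% (34.5 to 76.8) with a tumour. Their mix differed too, as the one led by Gm48099 held 5, 19, 18 and 3 nuclei. HSC/MPP-like nuclei were at 2 of 22 in non-tumour skull, 0 of 1 in tumour skull and 1 of 17 in tumour tibia.

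At promoters, T and NK cell genes were more open in tumour skull than in non-tumour skull, with a median log2 ratio of 1.33 (0.87 to 1.67, percentile 100) over 4 genes, from Nkg7 (2.11) and Bcl11b (1.65) to Skap1 (−0.58). NK and innate lymphoid markers were at 1.10 (0.79 to 1.58) and T-like markers at 0.18. B lineage promoters were less open in tumour skull, at −0.38 (−0.60 to −0.29, percentile 0) with 4 of 12 lower. Primary granule genes of neutrophil progenitors were at 1.00 (0.55 to 1.30) over 4 genes, type I interferon genes at 0.41 (0.25 to 0.60) and hypoxia and glycolysis genes at 0.45 (0.32 to 0.50), beside an all-gene median of 0.17. In tibia, T and NK cell promoters were at 0.16 (−0.07 to 0.60), B lineage promoters at 0.10 (−0.03 to 0.21) and MHC class II promoters at 0.23 (0.13 to 0.34, percentile 99.9). In mice with a tumour, T and NK cell promoters were more open in skull than in tibia, at 0.93 (0.58 to 1.25) in 4 of 5 members, and MHC class II (−0.24) and B lineage (−0.21) promoters less. Without a tumour, B lineage promoters were more open in skull than in tibia, at 0.40 (0.26 to 0.48, percentile 100), and T and NK cell promoters were at −0.19 (−0.48 to 0.13). AP-1 promoters were at 0.21, 0.17, 0.20 and 0.29 and G2 and M phase promoters at 0.29, 0.14, 0.02 and 0.21 over skull tumour, tibia tumour, non-tumour site and tumour site comparisons, against all-gene medians of 0.17, 0.07, 0.11 and 0.22. With fragments of all barcodes the T and NK cell median was 0.45 in skull and 0.21 between the tumour libraries, and with the joint call the skull B lineage median was 0.47. With barcodes under 30% mitochondrial UMIs, B lineage medians were −2.13, 1.39, 1.44 and −2.48 and MHC class II medians −1.70, 1.18, 0.72 and −2.22 in the order above, from as few as 498716 fragments in tumour skull. There, skull medians of type I interferon and hypoxia and glycolysis promoters were −2.04 and −1.02, so B lineage and MHC class II did not fall alone. All-gene medians were taken for the main set only. Under the alternative barcode sets, a shift of all promoters thus cannot be told from one of single lists. With fragments of all barcodes, AP-1 promoters were at −0.012 and G2 and M phase promoters at −0.0017 in the skull tumour comparison, and at −0.17 and −0.26 between the tumour libraries.

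**Figure D3:**
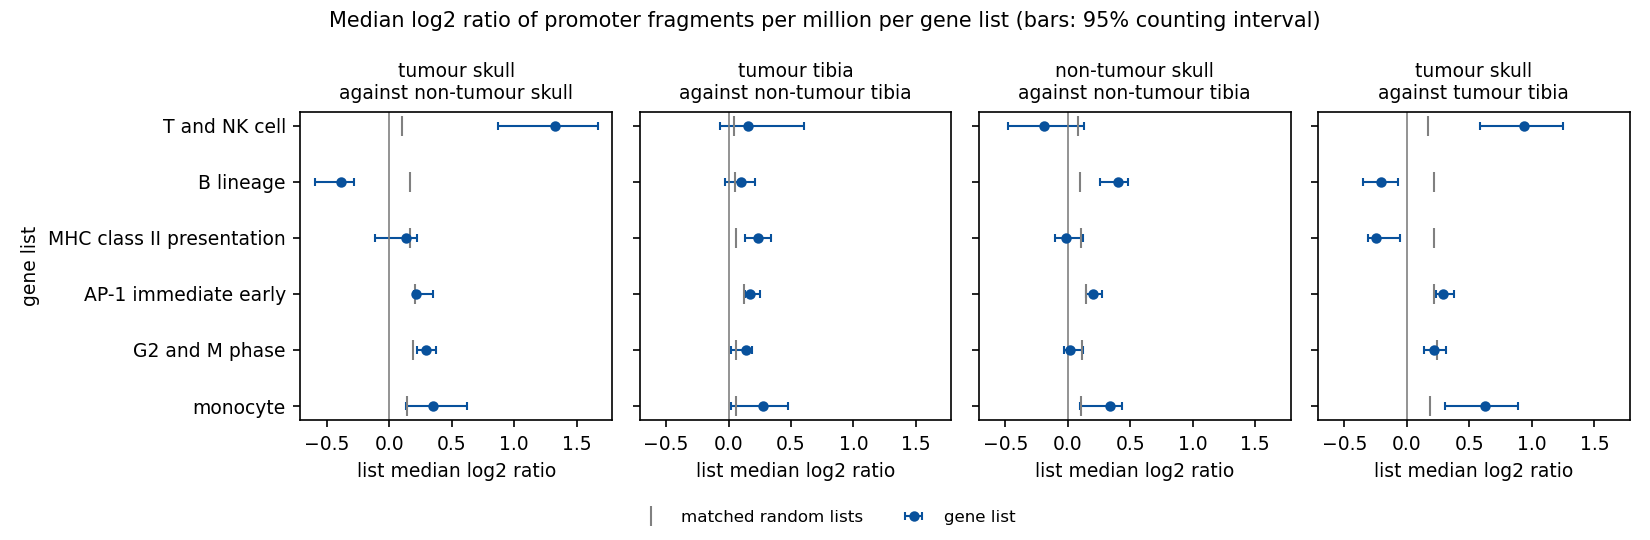
Median log2 ratio of promoter fragments scaled to total fragments (horizontal axis) for 6 gene lists in the 4 comparisons, with blue points for lists, bars for 95% counting intervals and grey ticks for the median of matched random lists. T and NK cell promoters were at 1.33 and B lineage promoters at −0.38 in tumour against non-tumour skull.

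The deposited peak lists held 56429 peaks in non-tumour skull, 50178 in tumour skull, 53484 in non-tumour tibia and 54526 in tumour tibia. The share overlapping a peak of another library by at least 1 base ran from 69.9% (peaks of non-tumour skull shared with tumour skull) to 80.0% (peaks of non-tumour tibia shared with non-tumour skull).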

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

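The tests in this part were chosen only after the results were seen, except the AP-1 median in the progenitor and dendritic group and the fold of the plasmacytoid dendritic markers. Differences between groups were not tested, since each group has 1 library.

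With the tumour, several lists had counting intervals on opposite sides of 0 in skull and tibia. Values here are the median over members of the skull change minus the tibia change in log2 units. Genes of the G2 and M phase differed by 1.38 over all nuclei and by 1.41 within B-lineage-like nuclei, with 18 of 18 members above 0 in both, but with every nucleus weighted equally the medians fell in both sites (−0.083 and −0.28), and with the joint call the skull median was −1.98. AP-1 genes differed by −0.85 over all nuclei, with 2 of 13 members above 0, and by −0.91 within B-lineage-like nuclei. Their skull change rests on the same non-tumour skull library as the site comparison without a tumour. Early lymphoid genes differed by −0.46 over all nuclei but by 0.031 within B-lineage-like nuclei. B lineage genes differed by −0.165 within B-lineage-like nuclei, while over all nuclei they fell in both sites (−0.35 and −0.17). All-gene medians over all nuclei were themselves −0.11 in skull and 0.10 in tibia. Over all nuclei, AP-1 genes in tibia (0.18) were at percentile 71.85 of matched random lists and early lymphoid genes in skull (−0.29) at 14.15. Neither side stood out from random lists, nor did the skull side of B lineage genes within B-lineage-like nuclei. The share of the unnamed low-UMI cluster rose with the tumour in skull and fell in tibia, a difference of 19.8 percentage points. In barcodes under 100 UMIs, which are not among the called nuclei, haemoglobin genes reached 1859 CPM (1783 to 1937) in tumour tibia against 909 in non-tumour tibia.

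T- and NK-like nuclei took a larger share in tumour skull than in non-tumour skull. A lower share of B-lineage nuclei would raise every other class alike, but plasmacytoid dendritic-like nuclei were at 0.669-fold (0.308 to 1.31), which argues against it as the whole cause. Shallow or rRNA-rich barcodes taken for these cells do not account for it either, because among nuclei of at least 1000 UMIs and under 15% rRNA-linked UMIs the ratio was 34.5 (11.3 to 141, 17 of 274 against 4 of 2227 nuclei). Blood left in the sample could not be told from marrow, since haemoglobin at 7.67 CPM (2.81 to 16.7) in barcodes under 100 UMIs against 309 in non-tumour skull says little where red cells were stained for sorting, and the antibody label of blood leukocytes was not analysed here. More T and NK cells in the marrow of the tumour-bearing mice may explain the share, as their promoters were more open by 1.33 (0.87 to 1.67) in chromatin. With fragments of all barcodes the value was 0.45, and no all-gene median was taken there. T-like marker promoters, however, were at 0.18 (−0.09 to 0.50) beside 0.17 for all genes. With 1 library this explanation stays a hypothesis.

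AP-1 and heat shock transcripts were higher in non-tumour skull than in non-tumour tibia. A different mix of cell classes is argued against as the whole cause by a median of 1.20 (1.15 to 1.37) within B-lineage-like nuclei, although with clusters given the same weights the median over all nuclei was 0.61. Handling of the non-tumour skull sample could have raised these genes, since the AP-1 median was also 1.36 (0.75 to 1.87) over 9 members in the progenitor and dendritic group, where matched random lists had a median of 0.50 (percentile 98.0), while heat shock at 1.0013 against 0.75 (percentile 75.4) did not stand out there. The group held different sub-clusters in the 2 libraries, with 51 skull and 1 tibia nuclei in the one with Il1b and 5 and 18 in one led by Gm48099. Its AP-1 median thus compares different cell mixes and cannot decide on handling. A difference between skull and tibia marrow could also have raised these genes, since the AP-1 median was 0.62 (0.52 to 0.77) between the tumour libraries. Site and preparation were confounded, so handling and site both stay open. The lower AP-1 and heat shock RNA of tumour skull was measured against the same non-tumour skull library, so handling of that sample stays open there too.

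Plasmacytoid dendritic-like nuclei took a larger share in tumour tibia than in non-tumour tibia. A lower share of B-lineage nuclei is argued against by the T- and NK-like ratio of 1.69 (1.24 to 2.33), far below the 8.09-fold of this class, and by shares of 10.2% and 8.86% at resolution 0.5, but less clearly without nuclei rich in ribosomal RNA, where T- and NK-like shares went from 0.994% to 4.35% (7 and 74 nuclei) and those of this class from 1.56% to 15.7% (11 and 267). The median marker fold of 24.8 (23.5 to 27.2) over B-lineage-like nuclei decides little on free RNA in other nuclei, as these markers named the class. Their sum was 23811 CPM in the class, 1160 in B-lineage-like nuclei and 778 in barcodes under 100 UMIs. That gap argues only against free RNA as the whole source of the markers in the class. It shares the limit of the fold, and 57.4% of the UMIs in those low barcodes were rRNA-linked, which lowers the 778. Whether the sample as a whole held more of these cells stays open, since their promoters were at 0.089 (−0.0021 to 0.17) and already open at a median of 36.7 CPM of fragments against 21.8 for all genes. Changes in the sort and in the marrow of tumour-bearing mice stay untested.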

How the results depend on the processing

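Most alternatives were listed before the data were examined, and those chosen only after the results were seen were the separate RNA and ATAC sets, leaving out nuclei rich in ribosomal RNA, with high doublet scores or of the unnamed cluster, scaling without mitochondrial and rRNA-linked genes, keeping large ATAC barcodes, and ATAC barcodes under 30% mitochondrial UMIs. Of RNA list medians under all alternatives, 1201 stayed within their counting interval, 137 moved out of it and 10 turned direction. For promoter medians these counts were 378, 183 and 58. A turn of direction was counted only where the reported interval was clear of no change. Other changes of sign are among the medians that stayed or moved, so the counts understate how often direction changed. The order-of-magnitude UMI rule left 32 of 32 values the same, as shares within their intervals or nuclei counts within 1.5-fold. Its minimums of 690, 528, 514 and 504 UMIs kept 2831, 644, 1082 and 2003 nuclei of the RNA call. It thus nearly repeats that call and says little on how firm the shares are. Leaving out the unnamed cluster left 66 of 66 medians within their intervals, and autosomes alone 12 of 12 peak shares. TMM factors left 121 medians within their intervals and moved 12, DESeq2 factors 129 and 4, and taking away 10% free RNA 128 and 5. A gene minimum of 10 UMIs left 120 and moved 13, and windows of 500 bases left 98 and moved 3. Of 97 shares and medians, leaving out the top 5% of doublet scores moved 1. The joint minimum of 1000 UMIs and 3000 fragments left too few nuclei for shares and medians, so for these 1000 UMIs were asked of the RNA call. A fit over both sites with site as a block, which leaves 1 residual degree of freedom, was not run. The erythroid background was not run, since no cluster was named erythroid-like and the haemoglobin counts that led the unnamed cluster came from 1 nucleus in each of 2 libraries. The depth of tumour skull limits both of its comparisons. Below, the skull and tibia tumour comparisons are tumour against non-tumour, the site comparisons are skull against tibia, and values run from the reported to the alternative one. The joint call and the higher minimums leave fewer nuclei, and for the other moves the cause was not tested.

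Nuclei by the joint call were 207, 9, 19 and 65 in non-tumour skull, tumour skull, non-tumour tibia and tumour tibia, against 3088, 662, 1100 and 2006 by RNA alone and 62, 3, 12 and 17 with at least 1000 UMIs and 3000 fragments. With the joint call, B-lineage-like shares were 95.2% in non-tumour skull, 33.3% in tumour skull, 89.5% in non-tumour tibia and 82.5% in tumour tibia. T- and NK-like shares were 1.45% in non-tumour skull and 22.2% in tumour skull. Unnamed low-UMI cluster shares were 0% in non-tumour skull, 44.4% in tumour skull, 5.26% in non-tumour tibia and 0% in tumour tibia. Plasmacytoid dendritic-like shares were 0.483% in non-tumour skull, 0% in tumour skull, 0% in non-tumour tibia and 4.76% in tumour tibia. Early lymphoid RNA in the skull tumour comparison moved from −0.29 to 0.18, AP-1 from −0.69 to −0.19 and G2 and M phase from 0.62 to −1.98. Heat shock RNA in the tibia tumour comparison moved from −0.26 to −0.41. Early lymphoid RNA in the non-tumour site comparison moved from 0.83 to −0.53, MHC class II from −0.81 to −1.38, AP-1 from 1.30 to 1.62 and heat shock from 0.77 to 1.11. G2 and M phase moved from −0.63 to −0.22. NF-kB promoters in the skull tumour comparison moved from 0.15 to −0.50, STAT5 from 0.10 to −0.56, heat shock from 0.32 to −0.82 and B lineage from −0.38 to 0.47. B lineage promoters in the non-tumour site comparison moved from 0.40 to 0.90. At a minimum of 1000 UMIs, T- and NK-like shares were 0.376% in non-tumour skull, 13.6% in tumour skull, 2.54% in non-tumour tibia and 6.03% in tumour tibia. B-lineage-like shares were 74.8% in tumour skull, 92.2% in non-tumour tibia and 70.5% in tumour tibia. Unnamed low-UMI cluster shares were 3.41% in tumour skull, 2.22% in non-tumour tibia and 0.0685% in tumour tibia. Plasmacytoid dendritic-like shares were 19.2% in tumour tibia. RNA of G2 and M phase genes in the skull tumour comparison moved from 0.62 to 0.77. Haemoglobin RNA in the non-tumour site comparison moved from −0.96 to 5.24 and G2 and M phase from −0.63 to −0.79.

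Without nuclei of over 15% rRNA-linked UMIs, B-lineage-like shares were 94.0% in non-tumour skull, 82.6% in tumour skull, 95.6% in non-tumour tibia and 76.4% in tumour tibia. T- and NK-like shares were 0.248% in non-tumour skull, 11.5% in tumour skull, 0.994% in non-tumour tibia and 4.35% in tumour tibia. Unnamed low-UMI cluster shares were 0.0708% in non-tumour skull, 1.30% in tumour skull, 1.70% in non-tumour tibia and 0.0588% in tumour tibia. Median G2 and M phase RNA in the skull tumour comparison moved from 0.62 to 0.88. AP-1 RNA in the non-tumour site comparison moved from 1.30 to 1.15 and G2 and M phase from −0.63 to −0.84. MHC class II RNA in the tumour site comparison moved from −0.29 to −0.15, AP-1 from 0.62 to 0.78, B lineage from −0.15 to 0.047 and G2 and M phase from 0.69 to 0.91. With doublets kept, all nuclei were clustered anew, and B-lineage-like shares were 73.6% in tumour skull and 90.6% in non-tumour tibia. This setting added 3 nuclei to tumour skull and 0 to non-tumour tibia, so the added nuclei cannot account for the move in tibia. At resolution 0.5, T- and NK-like shares were 26.6% in tumour skull and 10.2% in non-tumour tibia. B-lineage-like shares were 86.3% in non-tumour tibia. Plasmacytoid dendritic-like shares were 1.09% in non-tumour tibia and 11.6% in tumour tibia. At resolution 2, B-lineage-like shares were 86.0% in non-tumour tibia. Unnamed low-UMI cluster shares were 4.91% in non-tumour tibia. Plasmacytoid dendritic-like shares were 1.04% in non-tumour skull and 11.8% in tumour tibia. Thinning to 2000 UMIs gave an MHC class II UMI in 69.2% of B-lineage-like nuclei of non-tumour skull, 85.4% of non-tumour tibia and 81.5% of tumour tibia, and no thinning 60.8% in non-tumour skull and 76.1% in tumour tibia.

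With clusters given the same weights, AP-1 RNA in the skull tumour comparison moved from −0.69 to −0.25 and heat shock from −1.04 to −0.27. The G2 and M phase RNA in the tibia tumour comparison moved from −0.73 to −0.26. Early lymphoid RNA in the non-tumour site comparison moved from 0.83 to −0.22, MHC class II from −0.81 to −0.14, AP-1 from 1.30 to 0.61 and heat shock from 0.77 to 0.44. G2 and M phase moved from −0.63 to −0.83. MHC class II RNA in the tumour site comparison moved from −0.29 to 0.18, B lineage from −0.15 to 0.18 and G2 and M phase from 0.69 to 0.033. With every nucleus weighted equally, G2 and M phase RNA in the skull tumour comparison moved from 0.62 to −0.083. G2- and M-phase RNA in the tibia tumour comparison moved from −0.73 to −0.28. RNA of G2 and M phase genes in the non-tumour site comparison moved from −0.63 to −0.011. MHC class II RNA in the tumour site comparison moved from −0.29 to −0.51 and G2 and M phase from 0.69 to 0.37. By TMM factors, MHC class II RNA within B-lineage-like nuclei in the skull tumour comparison moved from 0.0056 to −0.16 and AP-1 from −0.80 to −0.97. MHC class II RNA within B-lineage-like nuclei in the non-tumour site comparison moved from −0.82 to −0.76. By DESeq2 factors, MHC class II RNA in the tumour site comparison moved from −0.29 to −0.19. With 10% free RNA taken away, AP-1 RNA within B-lineage-like nuclei in the non-tumour site comparison moved from 1.20 to 1.14. Scaled without mitochondrial and rRNA-linked genes, AP-1 RNA in the skull tumour comparison moved from −0.69 to −0.58 and G2 and M phase from 0.62 to 0.73. Heat shock RNA in the non-tumour site comparison moved from 0.77 to 0.67. AP-1 RNA within B-lineage-like nuclei in the non-tumour site comparison moved from 1.20 to 1.14. At a gene minimum of 200 UMIs, early lymphoid RNA within B-lineage-like nuclei in the non-tumour site comparison moved from 0.34 to −0.029.

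With ATAC barcodes under 30% mitochondrial UMIs, monocyte promoters in the skull tumour comparison moved from 0.35 to −2.10, MHC class II from 0.13 to −1.70, MHC class I from 0.18 to −1.38 and interferon from 0.41 to −2.04. NF-kB moved from 0.15 to −1.44, AP-1 from 0.21 to −1.10, STAT5 from 0.10 to −1.13 and homing from 0.16 to −2.49. Tolerance moved from 0.32 to −1.71, S phase from 0.32 to −1.64, heat shock from 0.32 to −1.48 and hypoxia from 0.45 to −1.02. B lineage moved from −0.38 to −2.13 and G2 and M phase from 0.29 to −1.75. All lists given here for the skull tumour comparison fell, and no all-gene median was taken for this setting. B lineage promoters in the tibia tumour comparison moved from 0.10 to 1.39 and MHC class II from 0.23 to 1.18. B lineage promoters in the non-tumour site comparison moved from 0.40 to 1.44 and MHC class II from −0.015 to 0.72. Stem cell promoters in the tumour site comparison moved from 0.23 to −0.76, MHC class II from −0.24 to −2.22, MHC class I from 0.24 to −1.16 and NF-kB from 0.34 to −0.90. AP-1 moved from 0.29 to −0.89, STAT5 from 0.31 to −1.14, homing from 0.26 to −2.34 and S phase from 0.26 to −1.61. Heat shock moved from 0.31 to −1.27, hypoxia from 0.31 to −1.09, B lineage from −0.21 to −2.48 and G2 and M phase from 0.21 to −1.61.

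With fragments of all barcodes, MHC class II promoters in the skull tumour comparison moved from 0.13 to −0.14, MHC class I from 0.18 to −0.10, NF-kB from 0.15 to −0.11 and AP-1 from 0.21 to −0.012. STAT5 moved from 0.10 to −0.19, homing from 0.16 to −0.14, heat shock from 0.32 to −0.020 and T and NK cell from 1.33 to 0.45. B lineage moved from −0.38 to −0.63 and G2 and M phase from 0.29 to −0.0017. B lineage promoters in the tibia tumour comparison moved from 0.10 to 0.22 and MHC class II from 0.23 to 0.35. Stem cell promoters in the tumour site comparison moved from 0.23 to −0.045, MHC class II from −0.24 to −0.68, MHC class I from 0.24 to −0.19 and interferon from 0.36 to −0.13. NF-kB moved from 0.34 to −0.15, AP-1 from 0.29 to −0.17, STAT5 from 0.31 to −0.21 and homing from 0.26 to −0.26. S phase moved from 0.26 to −0.24, heat shock from 0.31 to −0.19, hypoxia from 0.31 to −0.17 and T and NK cell from 0.93 to 0.21. B lineage moved from −0.21 to −0.62 and G2 and M phase from 0.21 to −0.26. With barcodes of 100000 fragments or more kept, STAT5 promoters in the skull tumour comparison moved from 0.10 to −0.061. B lineage promoters in the tibia tumour comparison moved from 0.10 to 0.26 and MHC class II from 0.23 to 0.40. Stem cell promoters in the tumour site comparison moved from 0.23 to −0.042, MHC class II from −0.24 to −0.50, MHC class I from 0.24 to −0.042 and STAT5 from 0.31 to −0.042. Homing moved from 0.26 to −0.080, S phase from 0.26 to −0.056, T and NK cell from 0.93 to 0.39 and B lineage from −0.21 to −0.50. G2 and M phase moved from 0.21 to −0.073. Scaling by fragments in promoter windows shifts every promoter of a comparison alike, so its turns of direction say nothing on single lists. Promoter windows held 46.5 per 100 fragments in non-tumour skull and 51.8 in tumour skull. Scaled in this way, NF-kB promoters in the skull tumour comparison moved from 0.15 to −0.0019 and STAT5 from 0.10 to −0.060. STAT5 promoters in the tibia tumour comparison moved from 0.035 to −0.043 and heat shock from 0.066 to −0.012. MHC class II promoters in the non-tumour site comparison moved from −0.015 to −0.13, S phase from 0.12 to −0.0026 and plasmacytoid dendritic markers from 0.088 to −0.030. MHC class II promoters in the tumour site comparison moved from −0.24 to −0.44 and B lineage from −0.21 to −0.40. With windows of 2 kb, T-like promoters in the non-tumour site comparison moved from 0.30 to −0.080. T and NK cell promoters in the tumour site comparison moved from 0.93 to 0.57.

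With an overlap of at least 50% of both peaks, peaks of non-tumour skull shared 69.4% with tumour skull, 75.4% with non-tumour tibia and 75.5% with tumour tibia. Peaks of tumour skull shared 78.1% with non-tumour skull, 76.6% with non-tumour tibia and 79.1% with tumour tibia. Peaks of non-tumour tibia shared 79.6% with non-tumour skull, 71.9% with tumour skull and 78.8% with tumour tibia. Peaks of tumour tibia shared 78.1% with non-tumour skull, 72.8% with tumour skull and 77.3% with non-tumour tibia.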

Other observations

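The values in this part rest on clusters and lists examined after the data were seen, and no explanation was tested for them. Counts run over non-tumour skull, tumour skull, non-tumour tibia and tumour tibia, with 3088, 659, 1100 and 1998 kept nuclei.

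Clusters of B-lineage-like nuclei were unevenly spread over the libraries. Mature B-like nuclei led by Cr2 and Fcer2a numbered 31, 55, 86 and 182, cycling nuclei 313, 45, 77 and 94, and nuclei with Il4i1, Egr3 and Cd83 numbered 412, 56, 82 and 72. Among sub-clusters left unnamed, one led by Il1rl1, Gata3, Rora and Areg, genes of type 2 innate lymphoid cells, held 0, 18, 2 and 3 nuclei, or 2.73% of tumour skull (1.63 to 4.28). Another led by Il23r, Cd163l1, Il1r1 and Icos held 2, 17, 0 and 10 nuclei, and one with Il1b and Lgals3 held 51, 17, 1 and 21.

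Some lists had fewer than 3 measured members, so their genes are given alone, over the skull tumour, tibia tumour, non-tumour site and tumour site comparisons. Of the neutrophil primary granule and progenitor list Gfi1 was at −0.68, −1.08, 0.11 and 0.50, and of the erythroid list Tfrc was at 0.53, 0.83, 0.05 and −0.25. The endothelial gene Pecam1 was at −0.17, −0.05, −0.54 and −0.67, and the neural gene L1cam at 0.09, −0.10, −0.77 and −0.57. Of stromal and bone genes, Alpl was at 0.12 in the skull tumour and 0.98 in the non-tumour site comparison. In the non-tumour site comparison the T and NK cell genes Skap1 and Lck were at −2.88 and −1.83. The mature neutrophil, megakaryocyte, basophil and mast cell, and macrophage lists had 0 measured members in RNA, as did haemoglobin in the tumour site comparison.

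Promoters of monocyte genes were at 0.35, 0.28, 0.34 and 0.62 and those of immune tolerance genes at 0.31, 0.30, 0.16 and 0.09 over the same comparisons. Basophil and mast cell promoters were at 0.82 (0.24 to 1.26) in the tibia tumour comparison over 3 genes, and early lymphoid promoters at −0.15, 0.10, 0.20 and 0.04. Within B-lineage-like nuclei the S phase medians were 0.04, −0.42, 0.26 and 0.88, and the type I interferon medians 0.31, 0.19, −0.67 and −0.35. Barcodes of at least 500 UMIs had 611, 213, 286 and 405 in common with those of at least 1000 fragments in their own library, against 9 to 25 in any other library.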
